A study of Mus musculus with 24 samples.

How the data were processed

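RNA was measured by bulk RNA sequencing in 24 mouse libraries, 12 of inner ear soft tissue from mice of 3 ages (4 per age) and 12 of cochlear organoids in 4 groups (3 per group). Per the labels, the mice were male C57BL6/J, the bone of the inner ear was removed, and the libraries were made with an unstranded TruSeq kit and sequenced on an Illumina HiSeq instrument. The titles of the organoid samples speak of a knockout of RBM25 and the protocol of a lentiviral knockdown, and the text follows the protocol. The control vector and the dose and duration of TNF are not given in the sources used here.

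The deposited count tables hold whole numbers of reads per gene, with no normalization by the authors, as counts. The deposited FPKM tables hold values that the authors scaled to gene length and library depth, in FPKM. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq, DESeq2 and the mm10 build, and their versions and settings are not given in the sources used here. The aging table lists 18440 genes and holds no mitochondrially encoded gene, and the organoid table lists 25190. Library totals were 30599012 to 38451292 counts in the aging table and 33802411 to 37048422 in the organoid table. The gene with the highest share of a library's counts was Ptgds in the inner ear, at up to 1.7%, and Igfbp5 or the mitochondrial gene COX1 in the organoids, at up to 2.65%. Counts of replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 16.5 to 90 between inner ear replicates and 4.73 to 36.7 between organoid replicates.

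Each count table was fitted as a whole with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group, TMM factors, the genes kept by filterByExpr (15525 in the inner ear and 15888 in the organoids), and robust quasi-likelihood dispersion. Each of the 8 comparisons was tested with the quasi-likelihood F-test, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with an adjusted p under 0.05 as the threshold. The interaction is the TNF effect with the knockdown minus that without it. CPM values use the TMM-scaled library size, and fitted log2 fold changes use edgeR's default shrinkage by a prior count. For a group with 0 counts, a fold is given as a lower bound against 3 counts over the group. For a group with 1 to 3 counts, the ratio is given with its exact 95% counting interval.

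Gene lists for cell types, immune responses and cell processes, 39 in all, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives except those said to be added later. In the inner ear 34 lists and in the organoids 30 lists had at least 4 genes tested. Shifts of lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of that experiment within each comparison, and again with an estimated correlation and with fry. List scores are the mean log2(CPM + 1) of a list's genes in a library. The named genes were Rbm25 and Tnf, the 8 genes with the highest and the 8 with the lowest log2 fold change that passed (4 and 4 in the comparison of 20 with 11 months, that of both treatments with the knockdown, and the interaction), and up to 3 members of each list with the smallest p. The genes with the largest changes had to reach a mean of 1 CPM in the higher group, to have no overlap between the libraries of the groups and to carry no predicted gene name. For the interaction the highest of the 4 group means was used and no condition on overlap was set. Genes with the largest changes were named in order of size as far as room allowed.

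Gene coordinates are those of the RefSeq annotation of GRCm38.p6, matched by Entrez identifier for 18321 genes of the aging table and 24318 of the organoid table. Overlaps of exons with other genes were taken from GENCODE vM21, because the unstranded libraries cannot assign reads in shared exons. The pipeline was tested on simulated data. For 20 against 3 months it called 61.2%, 77.6% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold, and 6.1% of its calls were unchanged genes. For TNF against control it called 65.7%, 73.1% and 93.9%, and 6.06% of its calls were unchanged genes.

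The alternatives were DESeq2's size factors in edgeR, no count filter, the DESeq2 1.42.0 Wald test, a fit of only the libraries compared, a replicate block, limma-trend on log2(FPKM + 1), a minimum fold of 1.5 with glmTreat, each library left out in turn, and a marrow score as a covariate in the inner ear. Mucosal and central neuron lists and mucosal, brain, and muscle and bone covariates were added later. Effects that share control libraries were compared with 20 simulations of unchanged groups and with the 3-month libraries split between the comparisons. Figures were drawn with matplotlib 3.10.9.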

Results

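Gene expression was measured by bulk RNA sequencing in 24 mouse samples from 2 experiments. In the aging experiment, the soft tissue held inside the bony inner ear was taken from male C57BL6/J mice aged 3, 11 and 20 months (n = 4 mice per age). In the organoid experiment, cell clusters grown in culture from the cochlear epithelium of newborn mice were left untreated, treated with TNF (tumour necrosis factor, an inflammatory cytokine), depleted of RBM25 (an RNA-binding protein that takes part in splicing) with a lentivirus, or given both (n = 3 libraries per group). The libraries held 30599012 to 38451292 counts in the aging table and 33802411 to 37048422 in the organoid table. The biological coefficient of variation was 19.8% among the inner ear samples and 8.04% among the organoid samples. Levels below are in CPM, counts scaled to the size of the library, as mean ± SD over the libraries of a group. The labels give 4 mice per age, whereas nothing says that the organoid replicates were separate cultures, so the p-values of the organoid experiment measure only the spread between these samples, which may be technical. Counting intervals and lower bounds on folds cover counting error only.

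Whether aging changed expression in the inner ear was addressed by comparing 20 with 3 months. Most genes of 7 immune lists were higher at 20 months, and 13 of 22 neuronal genes were lower. Cxcl13, which encodes a chemokine that attracts B cells, rose from 0.316 ± 0.149 to 11.2 ± 2.18 CPM (SD, n = 4; log2 fold change 5.14, SE 0.37, edgeR adjusted p = 9.38e-06). Mpeg1, which encodes a pore-forming protein of macrophages, rose from 21.9 ± 1.98 to 74.7 ± 16.5 CPM (log2 fold change 1.77, SE 0.14, edgeR adjusted p = 3.79e-05). H2-K1, a classical MHC class I gene, rose from 117 ± 18.7 to 285 ± 48.1 CPM (log2 fold change 1.29, SE 0.12, edgeR adjusted p = 9.43e-05). Calb2, which encodes the calcium-binding protein calretinin of auditory and vestibular neurons, fell from 2380 ± 269 to 1490 ± 66.9 CPM (log2 fold change -0.67, SE 0.08, edgeR adjusted p = 0.000308). Of 15525 genes tested, 1868 were higher and 1657 lower at 20 months by edgeR's quasi-likelihood test, and 565 of the higher and 74 of the lower genes changed at least 2-fold. Without replicate 3 of 20 months, which stood apart in markers of other tissues, the counts were 2010 and 1941. Without replicate 1 of 20 months they were 1221 and 990, and without replicate 1 of 3 months 1089 genes were lower. With covariates added after the data were seen, edgeR called 866 higher and 401 lower with the mucosal score, and 832 and 988 with the muscle and bone score.

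The largest increase from 3 to 20 months was that of Srd5a2, which encodes a steroid 5-alpha-reductase (chr 17:74014891-74047860, build mm10/GRCm38), from 3 counts over the 3-month libraries to 5.32 ± 1.6 CPM, a ratio of 237 with a 95% counting interval of 80.8 to 1150. An exon of Srd5a2 overlaps the annotated gene CT025731.1, so its reads cannot be assigned with certainty. Next in size were Cst7, a cysteine protease inhibitor of immune cells (log2 fold change 5.76), Cd8a, the co-receptor of cytotoxic T cells (log2 fold change 5.29), and Cxcl13 (chr 5:95956939-95961068). They were followed by the monocyte chemokine gene Ccl7 (log2 fold change 4.75), Ms4a4b (log2 fold change 4.7) and Jchain, which joins polymeric antibodies (log2 fold change 4.2). These genes passed edgeR's test at adjusted p values from 8.38e-06 for Srd5a2 to 0.00361 for Ccl7. The largest decreases were those of Prol1 (log2 fold change -5, from 3.33 ± 1.21 to 0.1 ± 0.0509 CPM), Bpifb1, a secreted protein of airway epithelium (log2 fold change -3.65), and the skeletal muscle actin Acta1 (log2 fold change -3.04). Smaller decreases were those of the chemokine receptor Ccr6 (log2 fold change -2.25), Rem2 (log2 fold change -2.22), the bone matrix gene Bglap2 (log2 fold change -2.13) and the muscle myosin light chain Myl1 (log2 fold change -2.07). In edgeR's test the adjusted p of Ccr6 was 0.0294, and its call was lost without replicate 2 or 3 of 3 months or replicate 1 or 4 of 20 months (adjusted p up to 0.086 with a library left out, and from 0.00239 to 0.135 over all its alternatives). Over their alternatives the highest adjusted p by edgeR, DESeq2 or limma was 0.0995 for Bpifb1, 0.44 for Acta1, 0.124 for Ccl7, 0.0602 for Prol1, 0.109 for Bglap2 and 0.0678 for Myl1, which all kept their calls with each library left out. Rbm25 did not pass at 20 months (135 ± 7.18 against 142 ± 15.3 CPM; edgeR adjusted p = 0.565), and neither did Tnf (0.292 ± 0.0657 against 0.138 ± 0.179 CPM; edgeR adjusted p = 0.379).

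The immune lists rose together at 20 months. Of 20 macrophage and monocyte genes 19 rose, among them Tyrobp, an adaptor of myeloid receptors (log2 fold change 1.51). Of 13 T and NK cell genes 10 rose, including Cd4 (log2 fold change 1.88). All 7 MHC class II genes rose, with H2-Eb1 and H2-Ab1 each at a log2 fold change of 1.92, and 13 of 14 MHC class I genes rose, with H2-D1 at 1.08. Of 28 interferon-stimulated genes 20 rose, including Trim30a (log2 fold change 1.83) and the antiviral enzyme gene Oas2 (log2 fold change 2.32). Of 31 NF-kB target genes 19 rose and 1 fell, with Ptgs2, the inducible cyclooxygenase, at a log2 fold change of 3.3 and the NF-kB inhibitor Nfkbia at 0.68. Of 12 complement genes 10 rose, including C1qc (log2 fold change 1.53) and C1qb (log2 fold change 1.4). Replicate 2 of 20 months stood apart in its complement score, 4.74 against 5.45 to 5.53 in the others of its age and 4.742 on average at 11 months, and without it 11 genes rose. Adjusted over the list alone, the counts higher were 19 for macrophages, 13 for T and NK cells, 7 for MHC class II, 13 for MHC class I, 26 for interferon, 22 for NF-kB and 11 for complement. The 7 lists passed camera's competitive test with preset correlation, at adjusted p values from 2.05e-29 for macrophages to 9.14e-11 for T and NK cells. None of these calls held with an estimated correlation, where camera gave adjusted p = 0.0521 for the macrophage, T and NK cell, NF-kB, MHC class II and complement lists, adjusted p = 0.0529 for MHC class I and adjusted p = 0.27 for the interferon list. The interferon genes called higher numbered 10, 13 and 12 without replicates 1, 2 and 4 of 3 months, 12 without replicate 1 of 20 months, 8 with the brain score and 4 with the muscle and bone score. With that last score 4 T and NK cell and 4 MHC class II genes were called, and with the mucosal score 4 of MHC class II. Beside this rise, the mucosal epithelium score (mean log2 CPM) was 2.46, 2.88, 1.68 and 2.83 in the 4 libraries of 20 months and 1.43 to 2.09 at 3 months.

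Of 22 neuronal genes 13 fell from 3 to 20 months and none rose (17 fell when adjusted over the list alone), among them Slc17a7, the vesicular glutamate transporter (log2 fold change -0.58), and Elavl4 (log2 fold change -0.6; adjusted p by edgeR, DESeq2 or limma up to 0.0712 over its alternatives). Of 20 Schwann cell and myelin genes 9 fell (10 adjusted over the list alone), including the peripheral myelin gene Pmp22 (log2 fold change -0.59). The camera adjusted p was 1.21e-09 for neurons and 3.46e-05 for Schwann cells, against adjusted p = 0.27 and adjusted p = 0.351 with an estimated correlation. Replicate 2 of 20 months had the lowest Schwann cell score, 7.41 against 8.01 to 8.04 in the others of its age, and without it 8 genes fell and 1 rose (median log2 fold change -0.26 in place of -0.35; camera adjusted p = 0.00462). With the mucosal score as a covariate 3 Schwann cell and 2 neuronal genes were called lower, and 7 neuronal genes without replicate 1 of 3 months or replicates 1 or 4 of 20 months. The hair cell list did not pass (camera adjusted p = 0.0592). Of its 29 genes 5 fell (4 adjusted over the list alone), with Cdh23, a component of the tip links of hair bundles, at 10.5 ± 1.11 against 21.9 ± 3.87 CPM (log2 fold change -1.05, edgeR adjusted p = 0.000397). Of 13 skeletal muscle genes 3 fell (4 adjusted over the list alone; median log2 fold change -1.74), and of 13 osteoblast and osteocyte genes 3 fell (3 adjusted over the list alone; median log2 fold change -0.42). By camera the adjusted p was 0.00203 for muscle and 0.0238 for osteoblasts, and with an estimated correlation adjusted p = 0.603 and adjusted p = 0.638. The osteoblast call was also lost without replicate 4 of 3 months or replicate 3 of 20 months (camera adjusted p up to 0.144 with a library left out, and up to 0.995 over all alternatives). The hair cell genes called lower were 2 without replicate 1 of 3 months and 3 without replicate 4 of 3 or of 20 months. Without replicate 3 of 3 months 6 muscle genes were called, and without replicate 2 of 20 months 5 osteoblast genes.

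Other lists moved in part at 20 months. Of 17 immediate early and heat shock genes 11 rose (11 adjusted over the list alone), led by the inducible HSP70 gene Hspa1b, from 9.6 ± 1.42 to 108 ± 44.9 CPM (log2 fold change 3.5, edgeR adjusted p = 6.94e-05), and the co-chaperone gene Dnajb1 (log2 fold change 0.95). Of 24 apoptosis and necroptosis genes 10 rose (11 adjusted over the list alone), among them the survival gene Mcl1 (log2 fold change 0.54) and the necroptosis effector Mlkl (log2 fold change 1.3). Of 15 genes of senescence and its secretory phenotype 7 rose (9 adjusted over the list alone), including Igfbp3 (log2 fold change 0.79). Of 38 nuclear genes of oxidative phosphorylation 7 fell (6 adjusted over the list alone), with Ndufv1 at a log2 fold change of -0.31, and 2 of 47 ribosomal protein genes rose (0 adjusted over the list alone). The camera adjusted p was 2.69e-13 for immediate early genes, 0.00132 for apoptosis, 0.000295 for senescence, 2.75e-05 for oxidative phosphorylation and 0.00313 for ribosomal proteins. With an estimated correlation camera gave adjusted p = 0.0646 for immediate early genes and for senescence, adjusted p = 0.27 for apoptosis, adjusted p = 0.583 for oxidative phosphorylation and adjusted p = 0.865 for ribosomal proteins. The ribosomal call was lost without replicate 1 of 3 months or replicate 1 of 20 months (camera adjusted p up to 0.121 with a library left out, and up to 0.878 over all alternatives). Of its genes 0 were called without either of these or replicate 4 of 20 months, 5 without replicate 3 of 20 months and 1 without any other. The senescence genes called were 3 without replicates 1 or 2 of 3 months or 1 of 20 months and 4 without replicate 4 of either age. Those of oxidative phosphorylation were 4 without replicate 3 of 3 months, and 2, 12 and 2 without replicates 1, 3 and 4 of 20 months. Over their alternatives the highest adjusted p by edgeR, DESeq2 or limma was 0.0898 for Igfbp3, 0.0726 for Mlkl and 0.053 for Ndufv1. With the mucosal score 2 apoptosis, 2 senescence and 6 immediate early genes and 0 of oxidative phosphorylation were called by edgeR.

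**Figure D1:**
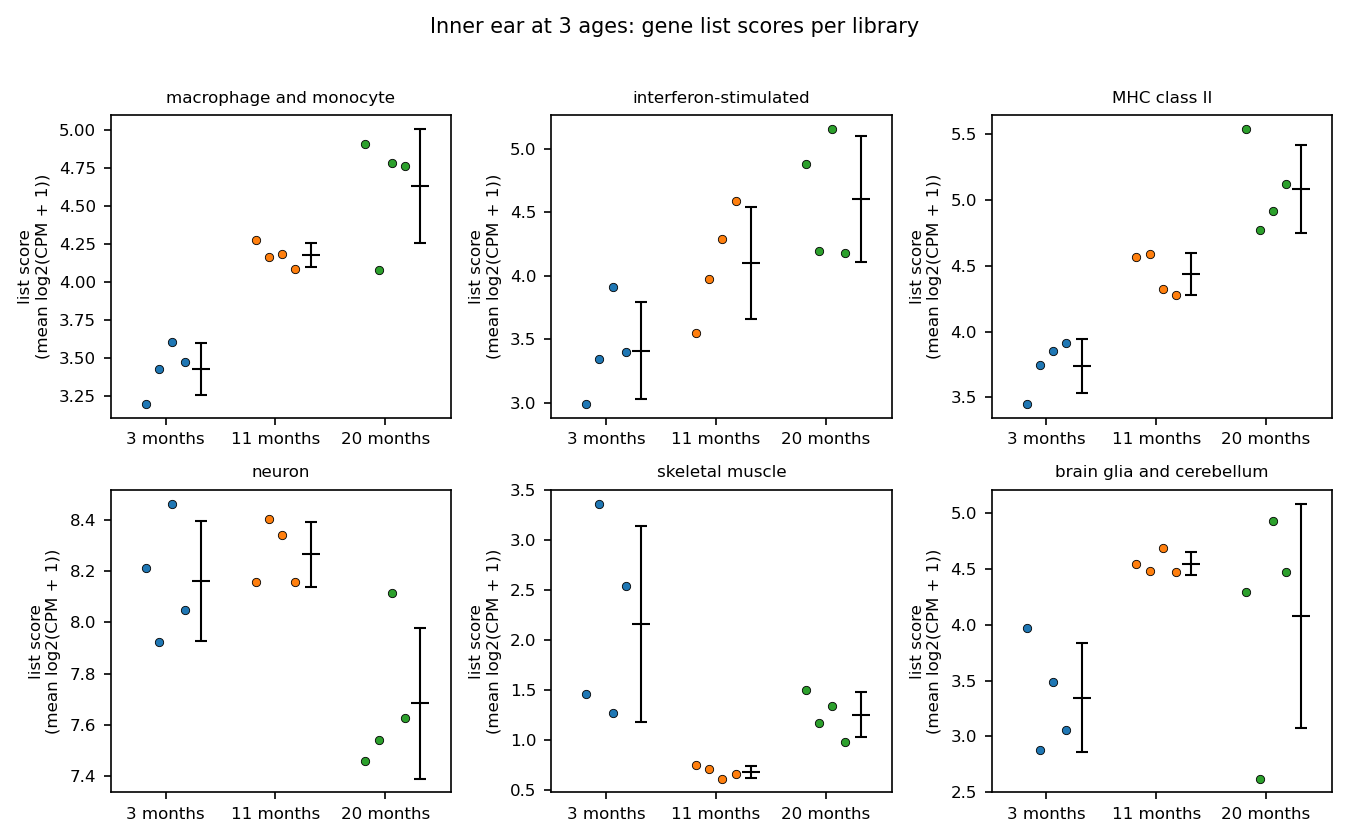
List scores of the inner ear libraries by age, 1 panel per gene list (macrophage and monocyte, interferon-stimulated, MHC class II, neuron, skeletal muscle, brain glia and cerebellum). The vertical axis is the mean log2(CPM + 1) of the list's genes and does not start at 0, points are libraries, and bars are the mean ± SD (n = 4). The macrophage score averaged 3.43 at 3 months, 4.18 at 11 months and 4.63 at 20 months, and the muscle score averaged 2.16, 0.677 and 1.25.

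At 11 months, 8 of 20 macrophage and 4 of 7 MHC class II genes were above their 3-month level, and 5 of 13 muscle and 2 of 13 osteoblast genes were below it. By camera the 4 lists passed with preset correlation but not with an estimated one (adjusted p from 0.138 to 0.185). The muscle score varied widely among the 3-month libraries, at 1.461, 3.364, 1.268 and 2.537 against 0.6096 to 0.742 at 11 months, and the osteoblast score was 3.447 to 4.369 against 2.652 to 2.877. Mpeg1 rose from 21.9 ± 1.98 to 49.5 ± 3.71 CPM (SD, n = 4; log2 fold change 1.18, SE 0.14, edgeR adjusted p = 0.00383). H2-Eb1, an MHC class II gene, rose from 14.4 ± 1.62 to 33.3 ± 1.19 CPM (log2 fold change 1.21, edgeR adjusted p = 0.0116). Acta1 fell from 16.4 ± 16.8 to 0.208 ± 0.125 CPM (log2 fold change -6.3, SE 0.95, edgeR adjusted p = 0.0165). By edgeR's test 152 genes were higher and 90 lower at 11 than at 3 months, 77 and 18 of them by at least 2-fold. Over their alternatives the calls of Mpeg1 and H2-Eb1 were lost at adjusted p up to 0.43 and 0.53 by edgeR, DESeq2 or limma. Every library left out lowered these counts by more than 1.5 times. They became 55 and 46, 47 and 20, 88 and 49, and 39 and 14 without replicates 1, 2, 3 and 4 of 3 months, and 49 and 27, 34 and 23, 29 and 9, and 49 and 20 without replicates 1, 2, 3 and 4 of 11 months. With the muscle and bone covariate, added later, edgeR called 0 genes higher and 1 lower, and with the brain score 12 and 7 (2808 genes had an unadjusted p under 0.05 without a covariate). These scores separated the ages, so the losses cannot tell age from tissue.

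The largest increases at 11 months were those of Srd5a2 (3.3 ± 0.378 CPM against 3 counts over the 3-month libraries, a ratio of 148 with a 95% counting interval of 50.4 to 721), Serpina9 (log2 fold change 3.39) and Calb1, the calbindin gene abundant in Purkinje cells (log2 fold change 3; 164 ± 18.6 against 20.5 ± 5.2 CPM). Next came Ngef, a neuronal exchange factor (log2 fold change 2.77), Cxcl13 (log2 fold change 2.65) and the stress hormone receptor gene Crhr1 (log2 fold change 2.46). The brain glia and cerebellum score was 4.469 to 4.692 at 11 months against 2.877 to 3.973 at 3 months. Exons of Serpina9 and Ngef overlap those of Gm28577 and Neu2, so their reads are uncertain. The largest decreases were those of Acta1 (chr 8:123891758-123894775), the muscle creatine kinase Ckm (log2 fold change -6.01), the fast troponin Tnnt3 (log2 fold change -5.35), the osteocalcin genes Bglap (log2 fold change -5.03) and Bglap2 (log2 fold change -4.14) and Bpifb1 (log2 fold change -4.04). Exons of Ckm overlap A930016O22Rik on the opposite strand. The edgeR adjusted p ranged from 5.48e-05 for Srd5a2 to 0.0383 for Crhr1. The calls of Calb1 and Crhr1 were lost without any 1 of the 8 libraries (edgeR adjusted p up to 0.0846 and 0.101). That of Ngef was lost without replicate 1, 2 or 3 of 3 months or 2 or 3 of 11 months (edgeR adjusted p up to 0.0777), and that of Acta1 without replicate 1, 3 or 4 of 11 months (up to 0.0777). The call of Ckm was lost without replicate 4 of 3 months or 2, 3 or 4 of 11 months (edgeR adjusted p up to 0.0912). Bglap lost it without any library but replicate 3 of 3 months (edgeR adjusted p up to 0.113), and Bpifb1 without replicate 2 or 4 of 3 months or any of 11 months (up to 0.0809). Over all alternatives the highest adjusted p by edgeR, DESeq2 or limma was 0.907 for Calb1, 0.952 for Crhr1, 0.514 for Ngef, 0.555 for Acta1, 0.883 for Ckm, 0.83 for Bglap and 0.979 for Bpifb1. For genes that kept their calls with each library left out it was 0.119 for Srd5a2, 0.732 for Serpina9, 0.308 for Cxcl13, 0.567 for Tnnt3 and 0.442 for Bglap2 (by edgeR, DESeq2 or limma). Rbm25 (129 ± 9.64 CPM; edgeR adjusted p = 0.407) and Tnf (0.186 ± 0.141 CPM; edgeR adjusted p = 0.815) did not pass.

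Among the lists at 11 months, 8 of 20 macrophage genes rose (18 adjusted over the list alone), including Trem2 (log2 fold change 1.17). Of 7 MHC class II genes 4 rose (4 adjusted over the list alone), and of 12 complement genes 3 rose (6 rose and 1 fell adjusted over the list alone), with C4b at a log2 fold change of 1.79. Of 13 T and NK cell genes 2 rose (9 adjusted over the list alone), and 1 each of 31 NF-kB targets and 28 interferon-stimulated genes rose (6 with 1 lower, and 5, adjusted over the list alone). None of 14 MHC class I genes passed (5 rose adjusted over the list alone). Of 13 muscle genes 5 fell (10 adjusted over the list alone; median log2 fold change -2.77), and of 13 osteoblast genes 2 fell (6 adjusted over the list alone). Of 30 collagen and matrix genes 5 fell (3 rose and 11 fell adjusted over the list alone), with Col11a2, a cartilage and tectorial membrane collagen, at a log2 fold change of -0.76. Beside these groups, 1 of 10 brain glia and cerebellum genes rose (4 adjusted over the list alone; median log2 fold change 1.26), namely Cbln1, a cerebellar synapse organiser (log2 fold change 1.6). Camera's adjusted p was 6.53e-25 for macrophages, 4.18e-09 for MHC class II, 2.61e-08 for complement, 1.59e-10 for T and NK cells, 3.9e-08 for NF-kB, 6.09e-11 for interferon, 4.73e-05 for MHC class I, 5.98e-14 for muscle, 4.18e-09 for osteoblasts, 4.73e-05 for collagen and 2.33e-06 for brain glia. With an estimated correlation camera gave adjusted p = 0.138 for macrophages, MHC class II, complement and NF-kB, adjusted p = 0.0959 for T and NK cells and adjusted p = 0.337 for interferon and MHC class I. In the same way camera gave adjusted p = 0.144 for muscle, adjusted p = 0.185 for osteoblasts and adjusted p = 0.252 for collagen and brain glia. Among the genes named, the call of Col11a2 was lost without any 1 library, that of Trem2 without any but replicate 3 of 3 months, and that of C4b without replicate 1, 2 or 4 of 3 months or 2 or 3 of 11 months (edgeR adjusted p up to 0.112, 0.0777 and 0.0737). Over all alternatives the adjusted p by edgeR, DESeq2 or limma reached 0.968, 0.878 and 0.876 for these, and 0.43 for Cbln1. Every library left out lowered the count of macrophage genes, to between 1 and 4, that of complement genes to 0 or 1, and that of collagen genes to between 0 and 3. The MHC class II genes called were 2 without replicates 1 or 2 of 3 months or any of 11 months. Without any library but replicate 3 of 3 months the T and NK cell genes were 0 or 1 and the osteoblast genes 1. The muscle genes were 2 without replicate 3 of 11 months and 3 without another library of 11 months or replicate 4 of 3 months. The NF-kB gene lost its call without any 1 library, and the interferon gene without any but replicate 3 of 3 months and replicate 1 of 11 months.

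From 11 to 20 months most neuronal genes fell and most MHC class I genes rose. Of 22 neuronal genes 16 fell (18 adjusted over the list alone; median log2 fold change -0.52), and 9 of 14 MHC class I genes rose (12 adjusted over the list alone; median log2 fold change 0.61). The genes with the largest increases were the pituitary hormone genes Gh (log2 fold change 7.62; 10.4 ± 11.2 against 0.0504 ± 0.0518 CPM, SD, n = 4) and Prl (a ratio of 182 to 1 count over the 11-month libraries, 95% counting interval 32.2 to 7220). They were followed by the mucin gene Muc4 (log2 fold change 5.76) and Ckm (log2 fold change 4.02). At 3 months Gh already stood at 1.2 to 8.16 CPM and Prl at 0.181 to 2.08 CPM. These values lay within the ranges at 20 months, 0.623 to 25.2 and 0.0623 to 2.97 CPM, and Ckm had fallen from 3 to 11 months. The increases of Gh and Prl thus hold against the 11-month libraries only. The largest decreases were those of Rem2 (log2 fold change -1.58), Asb15 (log2 fold change -1.39), Chac1 (log2 fold change -1.31) and Zfp941 (log2 fold change -1.15). The edgeR adjusted p lay between 0.00481 for Zfp941 and 0.0444 for Rem2, and exons of Muc4, Ckm and Zfp941 overlap those of Muc20, A930016O22Rik and Gm45785. Camera's adjusted p was 1.32e-14 for neurons and 4e-09 for MHC class I, and adjusted p = 0.243 for both with an estimated correlation. Without replicate 3 of 11 months 9 and 6 of these genes were called, and 10 neuronal genes without replicates 1 or 4 of 20 months. The neuron score of replicate 3 of 20 months was 8.114 against 7.46 to 7.626 in the others of its age and 8.158 to 8.404 at 11 months, and without this library 20 neuronal genes fell. Its central neuron and oligodendrocyte score was 4.54 against 3.07 to 4.1 in the others and 4.24 to 4.38 at 11 months. By edgeR's test 1222 genes were higher and 1226 lower at 20 than at 11 months, and 1818 and 1814 without replicate 3 of 20 months. The counts were 509 and 454, 778 and 751, and 579 and 565 without replicates 1, 2 and 4 of 20 months, and 490 and 754, 334 and 453, and 759 and 1020 without replicates 2, 3 and 4 of 11 months. With the mucosal score as a covariate, added after the data were seen, edgeR called 3 genes higher and 1 lower, none of them of these lists. The calls of Rem2 were lost without any 1 library, and those of Prl, Muc4 and Asb15 without replicate 3 of 11 months (edgeR adjusted p 0.12 at most for Rem2, 0.054 for Prl, 0.0503 for Muc4 and 0.06 for Asb15). That of Ckm was lost without replicate 2, 3 or 4 of 11 months or replicate 1 of 20 months (edgeR adjusted p up to 0.0793). Over all alternatives the highest adjusted p by edgeR, DESeq2 or limma was 0.517 for Rem2, 0.41 for Prl, 0.824 for Muc4, 0.364 for Asb15, 0.443 for Ckm, 0.403 for Gh, 0.48 for Chac1 and 0.311 for Zfp941. Rbm25 (edgeR adjusted p = 0.627) and Tnf (edgeR adjusted p = 0.621) did not pass.

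The changes at 11 and 20 months, both against the 3-month libraries, had a Pearson correlation across genes of 0.607 (Spearman 0.455), where genes are not independent replicates. Simulated unchanged groups against the same 3-month libraries gave 0.503 on average. The covariance was 0.214 against a simulated 0.051. All 199 genes called at both ages had the same direction, 140 higher and 59 lower, such as Cxcl13 and Acta1. Independent lists would share 18.3 and 9.61. The simulated groups shared at most 0, but unchanged groups give few calls, so that count is low by construction. With the 3-month libraries split between the comparisons, the correlation was 0.19 to 0.501 and the covariance 0.1 to 0.21. In these splits, with fewer libraries each, 14 to 29 genes were called at both ages in the same direction, and 1 went opposite ways in 2 of the 6.

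In the organoids, Rbm25 (Entrez 67039, chr 12:83632208-83683127, build mm10/GRCm38) stood at 142, 148 and 144 CPM in the control libraries, 150, 163 and 173 with TNF, 96.9, 94.2 and 92.7 with the knockdown, and 103, 122 and 108 with both. All 6 libraries labelled as knockdown were thus below all 6 others. The log2 fold change was -0.61 without TNF (SE 0.06, edgeR adjusted p = 1.01e-07) and -0.55 with TNF (SE 0.06, edgeR adjusted p = 4.61e-07). Rbm25 was higher with TNF than in controls (log2 fold change 0.16, edgeR adjusted p = 0.0315), a call lost without replicate 1 or 3 of the controls or replicate 2 or 3 of TNF (edgeR adjusted p up to 0.103). Over all alternatives of that call the adjusted p by edgeR, DESeq2 or limma ran from 0.00268 to 0.103. An exon of Gm29361 overlaps Rbm25 on the opposite strand, and the library kit did not keep strand. Tnf (chr 17:35199367-35202007) had 0 counts in the 6 libraries without TNF and stood at 1.22 ± 0.0928 CPM with TNF (SD, n = 3; at least 42.2-fold higher, against a floor of 3 counts over the group) and 1.86 ± 0.32 CPM with both (at least 67-fold higher than with knockdown alone).

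**Figure D2:**
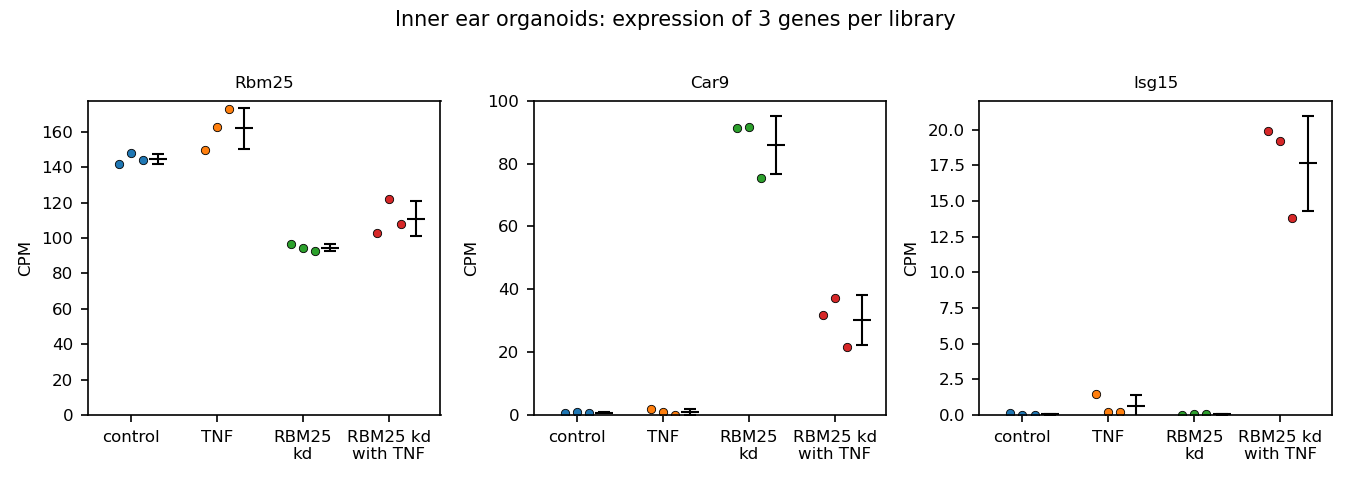
Level of Rbm25, Car9 and Isg15 in each organoid library in CPM, with the vertical axis from 0, points for libraries and bars for the mean ± SD (n = 3). Rbm25 lay between 92.7 and 122 CPM in the 6 knockdown libraries and between 142 and 173 CPM in the others, Car9 was at 21.7 CPM or above only in the knockdown libraries, and Isg15 was at 13.8 CPM or above only with both treatments.

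TNF raised NF-kB target and MHC genes. Nfkbia rose from 35.9 ± 1.13 to 619 ± 6.15 CPM (SD, n = 3; log2 fold change 4.11, SE 0.05, edgeR adjusted p = 1.72e-20). Cd74, the invariant chain of MHC class II, rose from 0.347 ± 0.123 to 481 ± 15.9 CPM (log2 fold change 10.42, SE 0.21, edgeR adjusted p = 1.07e-11). The matrix gene Fbln2 fell from 122 ± 2.39 to 2.73 ± 0.807 CPM (log2 fold change -5.47, SE 0.11, edgeR adjusted p = 1.88e-14). Of 15888 genes tested, edgeR's test called 3706 higher and 3840 lower with TNF, 722 and 680 of them by at least 2-fold.

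The largest increases with TNF were those of Ubd, a ubiquitin-like modifier (9.4 ± 3.24 CPM, at least 325-fold higher), Cd74 (chr 18:60803849-60812652), the complement gene C3 (log2 fold change 10.39, 304 ± 111 CPM), and H2-M2 (at least 85.3-fold higher). Next were Aif1 (at least 69.3-fold higher), Rspo1, a secreted activator of Wnt signalling (log2 fold change 9.12), and the serotonin transporter Slc6a4 (at least 52.4-fold higher). Ubd, H2-M2, Aif1 and Slc6a4 had 0 counts in the controls, and their bounds take 3 counts over the group as the floor. After Fbln2 (chr 6:91212460-91272540), the largest decreases were those of Lypd1 (log2 fold change -5.05), Hpca (log2 fold change -4.23), the neuronal nitric oxide synthase Nos1 (log2 fold change -3.81), Bcan, a matrix proteoglycan (log2 fold change -3.64), and Shisa8 (log2 fold change -3.39). All passed edgeR's test, with the highest adjusted p, 1.29e-05, for Ubd. Exons of Cd74, Lypd1, Hpca and Nos1 overlap Mir5107, Gpr39, Tmem54 and Gm26995, so their reads are uncertain.

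Of 31 NF-kB targets 28 rose and 1 fell with TNF, including the apoptosis inhibitor Birc3 (log2 fold change 3.86) and Tnip1 (log2 fold change 3.13). Of 12 MHC class I genes 11 rose and 1 fell, with H2-K1 at a log2 fold change of 2.63, and all 7 MHC class II genes rose (median log2 fold change 5.73). Adjusted over the list alone, the counts were 29 higher and 1 lower for NF-kB, 11 and 1 for MHC class I and 7 for MHC class II. The 3 lists passed camera at adjusted p = 1.63e-79, 4.6e-38 and 1.3e-28, and also with an estimated correlation, at adjusted p = 4.71e-05, 0.000462 and 0.00228. Of 27 interferon-stimulated genes 19 rose and 2 fell (20 and 2 adjusted over the list alone), with Ddx58, a sensor of viral RNA, at a log2 fold change of 1.82. Of 8 complement genes 6 rose (6 adjusted over the list alone), and all 47 ribosomal protein genes rose (47 adjusted over the list alone; median log2 fold change 0.51, with Rplp0 at 0.73). Of 18 cholesterol synthesis genes 13 rose (13 adjusted over the list alone). Of 38 nuclear genes of oxidative phosphorylation 29 rose (32 adjusted over the list alone), and of 14 Wnt targets 8 rose and 1 fell (9 and 2 adjusted over the list alone), with Myc at a log2 fold change of 2.87. Of 17 immediate early and heat shock genes 12 fell and 3 rose (12 and 3 adjusted over the list alone), among them Fos (log2 fold change -1.32) and Fosb (log2 fold change -2.25). Camera's adjusted p was 2.86e-10 for interferon, 6.19e-05 for complement, 1.69e-18 for ribosomal proteins, 1.43e-05 for cholesterol synthesis, 0.00284 for oxidative phosphorylation, 0.00855 for Wnt and 1.18e-05 for immediate early genes. These calls were lost with an estimated correlation, where camera gave adjusted p = 0.226 for interferon, adjusted p = 0.3 for complement, adjusted p = 0.402 for ribosomal proteins, adjusted p = 0.654 for oxidative phosphorylation and adjusted p = 0.263 for cholesterol synthesis, Wnt and immediate early genes.

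The inner ear lists did not pass for TNF. Of 22 supporting cell and tectorial membrane genes 5 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.242). The tectorial membrane genes Otog (5220 ± 138 to 1570 ± 180 CPM; log2 fold change -1.73, SE 0.07) and Otoa (log2 fold change -1.26) fell, as did Sox2, a transcription factor of supporting cells (log2 fold change -0.76). Of 28 hair cell genes 1 rose and 5 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.293). Of 30 collagen and matrix genes 4 rose and 11 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.0507), Sparc among the latter (log2 fold change -1.11). Without any 1 control library 3 hair cell genes fell and 2 collagen genes rose, and without replicate 2 of TNF 3 hair cell genes fell.

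The RBM25 knockdown raised 14 of 16 hypoxia and glycolysis, 26 of 33 cell cycle, 18 of 30 collagen and matrix and 23 of 28 hair cell genes, and lowered 1, 0, 3 and 5. By camera these lists passed with preset correlation but not with an estimated one (adjusted p = 0.569 for hypoxia and cell cycle and adjusted p = 0.812 for the others). Car9, a carbonic anhydrase induced by hypoxia, rose from 0.773 ± 0.106 to 86 ± 9.18 CPM (SD, n = 3; log2 fold change 6.79, SE 0.45, edgeR adjusted p = 2.05e-06). Mki67, a marker of dividing cells, rose from 0.482 ± 0.211 to 4.69 ± 0.947 CPM (log2 fold change 3.27, SE 0.28, edgeR adjusted p = 1.45e-08). Gjb2, which encodes the gap junction protein connexin 26 of supporting cells, fell from 590 ± 10.5 to 185 ± 16.9 CPM (log2 fold change -1.67, SE 0.09, edgeR adjusted p = 5.68e-10). By edgeR's test 3870 genes were higher and 4488 lower with the knockdown than in controls, 1578 and 774 of them by at least 2-fold. The control vector is not given in the sources used here.

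After Car9 (chr 4:43507026-43513729), the largest increases with knockdown were those of the transporter gene Slc6a13 (log2 fold change 5.77), the secretogranin gene Scg2 (log2 fold change 5.7), and Ndufa4l2 (log2 fold change 5.58). Next were Mab21l4 (log2 fold change 5.36), Abca13 (log2 fold change 5.25), Cox4i2, a cytochrome oxidase subunit (log2 fold change 5.16), and Mgarp (log2 fold change 4.96). The largest decreases were those of the aldehyde oxidase Aox4 (log2 fold change -4.65), Capn3 (log2 fold change -4.33) and Slc26a5, which encodes prestin, the motor protein of outer hair cells (log2 fold change -4.09; 0.102 ± 0.0459 against 1.79 ± 0.337 CPM). Below them were Ikzf3 (log2 fold change -3.9), Dlgap1 (log2 fold change -3.77) and P2rx5 (log2 fold change -3.74). The edgeR adjusted p was 0.00571 for Cox4i2, 0.00176 for Ndufa4l2 and 1.08e-05 or lower for the others. Exons of Car9, Ndufa4l2, Aox4, Capn3 and Dlgap1 overlap Gm12454, Shmt2, Gm15759, Ganc and AC079441.1, and the symbol Mab21l4 was not matched to the exon table.

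Of 16 hypoxia and glycolysis genes 14 rose and 1 fell with the knockdown (14 and 1 adjusted over the list alone), including the glycolytic enzymes Pgam1 (log2 fold change 1.39) and Pfkl (log2 fold change 1.58). Of 33 cell cycle genes 26 rose (29 adjusted over the list alone), with the mitotic kinase Cdk1 at a log2 fold change of 2.38. Of 28 hair cell genes 23 rose and 5 fell (23 and 5 adjusted over the list alone), where Cib2 rose (log2 fold change 1.73) and Ush1c fell (log2 fold change -0.72), both with exons overlapping an opposite gene. Of 30 collagen and matrix genes 18 rose and 3 fell (19 and 3 adjusted over the list alone), with Col9a1 at a log2 fold change of 1.08, and of 16 mesenchymal genes 8 rose and 3 fell (8 and 3 adjusted over the list alone), with Vim at 1.53. Of 38 nuclear genes of oxidative phosphorylation 18 rose and 1 fell (18 and 1 adjusted over the list alone). The camera test gave adjusted p = 1.7e-11 for hypoxia, 4.9e-05 for cell cycle, 0.000111 for hair cells, 0.000175 for collagen, 0.0439 for mesenchymal genes and 0.0332 for oxidative phosphorylation. No call held with an estimated correlation, where camera gave adjusted p = 0.569 for hypoxia and cell cycle, adjusted p = 0.812 for hair cells, collagen and mesenchymal genes and adjusted p = 0.832 for oxidative phosphorylation. The mesenchymal call was lost without any 1 control library, and that of oxidative phosphorylation without replicate 1 of the controls or replicate 3 of the knockdown (camera adjusted p up to 0.0731 and 0.0799, and over all alternatives up to 0.812 and 0.832). Without replicate 2 of the knockdown 1 mesenchymal gene fell. Of 42 splicing factor genes 7 rose and 15 fell (7 and 16 adjusted over the list alone; camera adjusted p = 0.387). Of 27 interferon-stimulated genes 4 rose and 8 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.404).

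With TNF present, the knockdown raised 25 of 27 interferon-stimulated genes above their level with TNF alone, and 15 of 17 immediate early and heat shock genes. With an estimated correlation camera passed the former list (adjusted p = 0.0342) but not the latter (adjusted p = 0.129). Ifit3, an antiviral interferon-induced gene, stood at 26.5 ± 1.02 CPM with both against 1.24 ± 0.17 CPM with TNF (SD, n = 3; log2 fold change 4.42, SE 0.2, edgeR adjusted p = 7.16e-12). Fos rose from 212 ± 23.6 to 589 ± 3.75 CPM (log2 fold change 1.47, SE 0.07, edgeR adjusted p = 6.6e-12). Slc26a5 fell from 1.18 ± 0.109 to 0.0809 ± 0.0471 CPM (log2 fold change -3.82, SE 0.43, edgeR adjusted p = 6.17e-07). By edgeR's test 4035 genes were higher and 4279 lower, 1499 and 551 of them by at least 2-fold.

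The largest increases of this comparison were those of the bone matrix gene Ibsp (50.4 ± 48.8 CPM, at least 1810-fold higher than the 0 counts with TNF), Scg2 (log2 fold change 8.02), the interferon-induced chemokine gene Cxcl9 (ratio 354 to 1 count, 95% counting interval 63.1 to 14000) and Oas1g (ratio 129 to 2 counts, interval 35.3 to 1070). They were followed by Oas2 (ratio 129 to 1 count, interval 22.7 to 5130), Sct (log2 fold change 5.57) and Ifi44 (log2 fold change 5.49; chr 3:151730922-151749910). The largest decreases were those of Car10 (log2 fold change -3.94), Ikzf3 (log2 fold change -3.89), Slc26a5, Tmem233 (log2 fold change -3.44), Aox4 (log2 fold change -3.21) and St8sia6 (log2 fold change -3.14). The edgeR adjusted p was 0.0135 for Ibsp and 6.38e-05 or lower for the others, and exons of Aox4 and St8sia6 overlap Gm15759 and Gm37126 on the opposite strand. The call of Ibsp was lost when only the libraries compared were fitted (edgeR adjusted p = 0.197, the highest over its alternatives). Tnf did not differ by this test (log2 fold change 0.6, edgeR adjusted p = 0.105).

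Of 27 interferon-stimulated genes 25 rose and 1 fell (25 and 1 adjusted over the list alone; median log2 fold change 3.09), and camera passed both at adjusted p = 3.6e-20 and with an estimated correlation at adjusted p = 0.0342. Of 17 immediate early and heat shock genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with Fosb at a log2 fold change of 2.56. Of 16 hypoxia genes 15 rose and 1 fell (15 and 1 adjusted over the list alone), and of 30 collagen genes 19 rose and 2 fell (20 and 2 adjusted over the list alone). Of 33 cell cycle genes 21 rose and 1 fell (22 and 1 adjusted over the list alone), and of 28 hair cell genes 21 rose and 5 fell (22 and 5 adjusted over the list alone). Pgam1 (log2 fold change 1.03), Col11a1 (log2 fold change 1.27) and Cdk1 (log2 fold change 1.69) were examples. Of 12 MHC class I genes 9 rose (9 adjusted over the list alone), with H2-D1 at a log2 fold change of 0.66, and of 8 complement genes 7 rose (7 adjusted over the list alone). Camera's adjusted p was 9.57e-13 for immediate early genes, 2.68e-06 for hypoxia and for collagen, 0.0089 for cell cycle and for hair cells, 0.00251 for MHC class I and 0.0057 for complement. These calls were lost with an estimated correlation, where camera gave adjusted p = 0.129 for immediate early genes, adjusted p = 0.498 for hypoxia and complement, adjusted p = 0.437 for collagen and cell cycle, adjusted p = 0.58 for hair cells and adjusted p = 0.429 for MHC class I. Of 31 NF-kB targets 15 rose and 5 fell (15 and 6 adjusted over the list alone; camera adjusted p = 0.2).

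Within the knockdown, TNF raised NF-kB target, interferon-stimulated and MHC genes. Saa3, an acute phase protein, reached 15.2 ± 6.35 CPM with both (SD, n = 3; at least 548-fold higher than the 0 counts with knockdown), and Ibsp (ratio 5450 to 1 count, interval 977 to 215000), H2-Aa (ratio 2930 to 2 counts, interval 810 to 24200) and H2-M2 (at least 248-fold higher) followed. The largest decreases were those of the cartilage gene Cilp (log2 fold change -5.16), Fbln2 (log2 fold change -4.29), the potassium channel Kcnt1 (log2 fold change -3.83) and the cartilage matrix gene Matn1 (log2 fold change -3.81). The edgeR adjusted p was at most 0.0163, for Ibsp, whose call was lost without any 1 knockdown library (edgeR adjusted p up to 0.098, the highest over its alternatives). By edgeR's test 3630 genes were higher and 3493 lower. Of 31 NF-kB targets 28 rose and 1 fell (30 and 1 adjusted over the list alone), and of 27 interferon-stimulated genes 26 rose and 1 fell (26 and 1 adjusted over the list alone). All 12 MHC class I and 7 MHC class II genes rose (12 and 7 adjusted over the list alone). For these lists camera gave adjusted p = 4.65e-88, 3.77e-57, 5.26e-61 and 4.16e-31, and with an estimated correlation adjusted p = 1.58e-05, 0.00154, 0.000102 and 0.00286. Of 28 hair cell genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), at a camera adjusted p of 0.0092 and adjusted p = 0.694 with an estimated correlation. Rbm25 was higher with both than with knockdown alone (log2 fold change 0.23, SE 0.06, edgeR adjusted p = 0.00471).

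**Figure D3:**
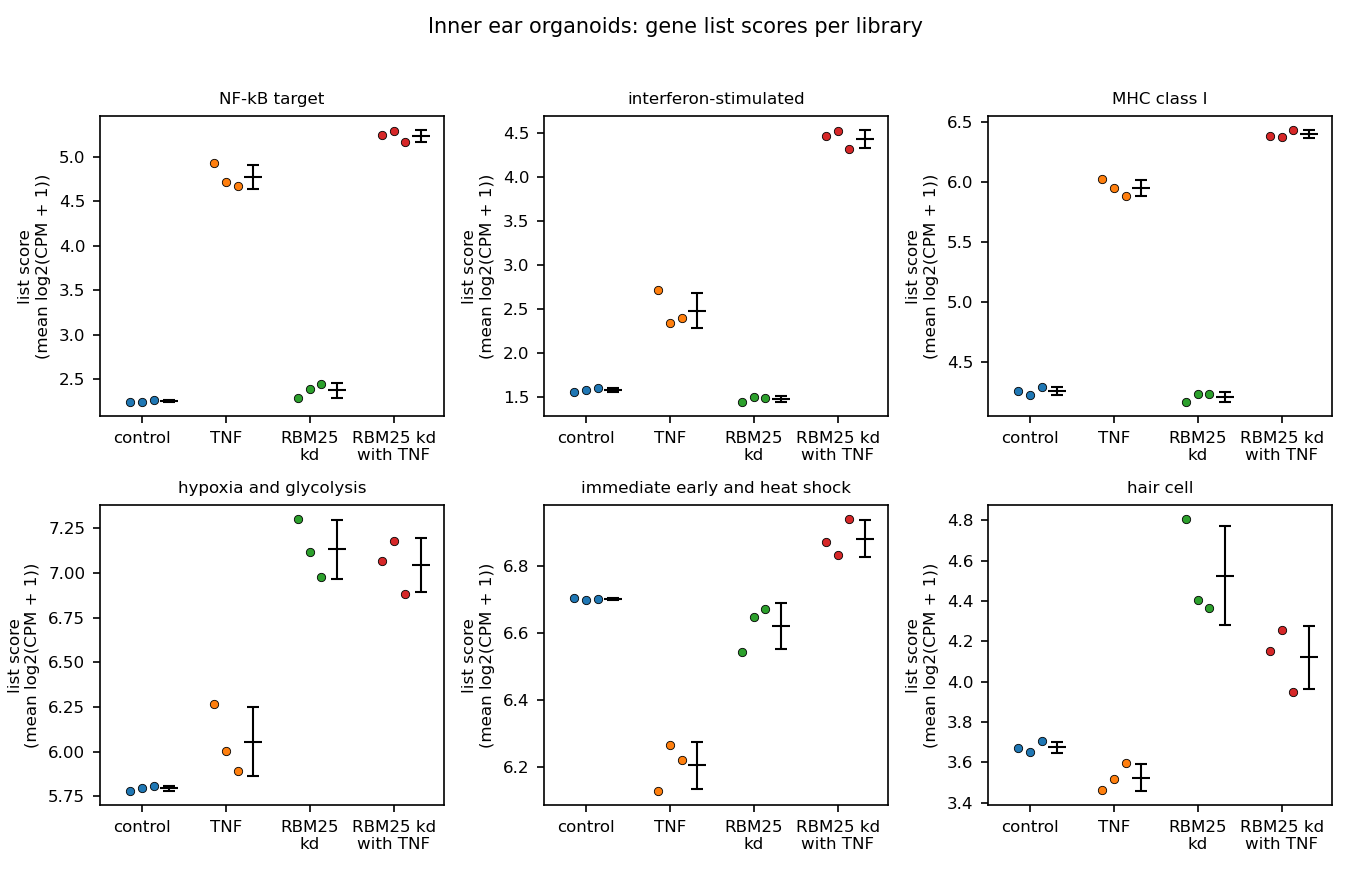
List scores of the organoid libraries, 1 panel per gene list (NF-kB target, interferon-stimulated, MHC class I, hypoxia and glycolysis, immediate early and heat shock, hair cell). The vertical axis is the mean log2(CPM + 1) of the list's genes, points are libraries, and bars are the mean ± SD (n = 3). The interferon score averaged 1.58 in controls, 2.48 with TNF, 1.47 with the knockdown and 4.43 with both.

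The interaction tested the TNF effect with the knockdown minus that without it. The interferon-stimulated list gave the clearest difference, with 19 of 27 genes having a larger response to TNF with the knockdown and none a smaller 1 (21 adjusted over the list alone; median log2 difference 2.81). Of 17 immediate early and heat shock genes 13 had a positive difference (16 adjusted over the list alone; median 0.74), Fos and Fosb having fallen with TNF in controls. Camera passed both lists, at adjusted p = 9.66e-41 and 3.26e-37, and with an estimated correlation at adjusted p = 0.00537 for both. The largest positive differences were those of Cyp1a1 (8.75 on the log2 scale), Oas1g (7.95), Usp18 (6.34) and Gpnmb (6.14). The largest negative ones were those of Cilp (-4.06), Camkv (-3.59), Car10 (-3.4) and Lcp1 (-3.24). The mean of Usp18 was 0.0481 CPM in controls, 0.176 with TNF, 0.0191 with the knockdown and 6.15 ± 0.491 with both (SD, n = 3). With both, Gpnmb stood near its control level, at 1.01 against 0.86 CPM, and Cyp1a1 at 1.68 ± 1.62 against 0.328. Each had 2 counts with the knockdown alone. These fitted differences depend on the prior count, because the lowest groups hold few counts, and exons of Usp18 and Lcp1 overlap opposite genes. The edgeR adjusted p ran from 6.98e-05 for Camkv to 0.0496 for Lcp1. The call of Cyp1a1 was lost without any library but replicate 2 of the group with both, and that of Lcp1 without any but replicate 3 of the controls and replicate 3 of TNF (edgeR adjusted p up to 0.102 and 0.134). Car10 kept its call only without replicate 2 of the controls, replicate 1 of TNF or replicates 2 or 3 of the knockdown, and Cilp lost it without replicate 2 of TNF (edgeR adjusted p up to 0.365 and 0.0692, the highest over their alternatives). In all, 1198 genes had a positive and 764 a negative difference in edgeR's test, 61.1% positive, against 53.7% with DESeq2's size factors and 47.8% without the count filter. A positive difference is a larger rise, a smaller fall or a fall turned into a rise with TNF. Among genes raised by TNF in controls, 190 had a called difference towards a larger and 477 towards a smaller or opposite response, and among genes lowered 67 and 739. Genes chosen by their response in controls lean towards smaller responses by this choice alone. Genes with a positive difference numbered 789 without replicate 1 of the controls, and 637 and 677 without replicates 1 and 3 of the group with both. Those with a negative difference numbered 432 and 477 without replicates 1 and 2 of the controls, 486 without replicate 2 of the knockdown and 1158 without replicate 2 of the group with both. Rbm25 itself showed no interaction (0.07 on the log2 scale, SE 0.09, edgeR adjusted p = 0.683).

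Other lists differed less. Of 12 MHC class I genes 6 had a positive difference (9 adjusted over the list alone), and of 13 senescence genes 4 (4 adjusted over the list alone). Of 16 hypoxia genes 7 had a negative difference (7 adjusted over the list alone), as did 5 of 18 cholesterol synthesis genes (5, with 1 positive, adjusted over the list alone). So did 2 of 33 cell cycle genes (2 adjusted over the list alone) and 2 of 28 hair cell genes (2 adjusted over the list alone). By camera's test the adjusted p was 1e-07 for MHC class I, 0.0294 for senescence, 2.42e-05 for hypoxia, 0.0072 for cholesterol synthesis, 0.00148 for cell cycle and 0.0128 for hair cells. With an estimated correlation camera gave adjusted p = 0.0578 for MHC class I, adjusted p = 0.454 for senescence and cell cycle, adjusted p = 0.694 for hypoxia, adjusted p = 0.613 for cholesterol synthesis and adjusted p = 0.944 for hair cells. The senescence call was lost without replicate 2 of TNF or replicate 1 of the knockdown and the hair cell call without replicate 3 of TNF, replicate 1 of the knockdown or replicate 3 of the group with both (camera adjusted p up to 0.0596 and 0.505). The NF-kB list did not differ by this test (6 of 31 positive and 4 negative, 6 and 5 adjusted over the list alone; camera adjusted p = 0.899). Without replicates 1, 2 and 3 of the controls 2, 1 and 2 NF-kB genes were negative. The hypoxia genes called were 4 and 3 without replicates 1 and 2 of the controls, and those of cholesterol synthesis 3 without any 1 control library or replicates 2 or 3 of the knockdown. For cell cycle they were 4, 5 and 5 without replicate 3 of the controls, 3 of TNF or 2 of the group with both. For hair cells they were 4 without replicate 3 of the knockdown or 2 of the group with both, and 1 without any control or TNF library, replicate 2 of the knockdown or replicate 1 of the group with both.

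Across genes, the effect of the knockdown without TNF correlated with that with TNF at r = 0.759 (Spearman 0.756), comparisons that share no library. Of 6001 genes called in both, 97.1% had the same direction, such as Car9 and Ikzf3, with 2782 higher and 3047 lower where independent lists would share 982.8 and 1209, and 172 went opposite ways. The TNF effect without and with the knockdown correlated across genes at r = 0.789 (Spearman 0.668). Of 4994 genes called in both 96.4% had the same direction, such as Cd74 and Fbln2, with 2507 higher and 2306 lower where independent lists would share 846.7 and 844.2, and 181 opposite. Of the genes called for TNF, the addition of the knockdown moved 2788 in the opposite direction, 774 further up and 1009 further down. Independent lists would share 941.2 and 1034 of the latter kinds, and no such value is given here for the opposite moves. The 20 simulations of unchanged groups gave at most 1 opposite and 0 in the same direction. Unchanged groups give few calls, so these counts are low by construction and set no scale for the real ones. The correlation was -0.0806, against a simulated -0.503 from the shared TNF libraries, which may also account for part of the opposite moves, and the covariance was -0.057 against a simulated -0.0322.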

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

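The tests of a mislabelled library, of different tissue in that library, of a response to the vector alone and of a stronger response to TNF in general were chosen after the results were seen, as were the mucosal and brain covariates and the choice of the 7 immune lists with their bounds.

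Macrophage, T and NK cell, MHC class I and II, interferon, NF-kB and complement genes were higher at 20 than at 3 months, by camera calls with preset correlation that were all lost with an estimated one (adjusted p from 0.0521 to 0.27). Mucosal tissue, blood or bone marrow, and central nervous tissue carried over in dissection could each bring such genes. With the mucosal score as a covariate 7 of the 7 lists kept their camera call at 88.7% to 127% of their median log2 fold change. The mucosal list itself went from 3 genes called higher, or 13 without replicate 3 of 20 months, to 0. Its own genes make up the score, so this loss was fixed in advance and tests no other genes. With the marrow score 7 of the 7 immune lists kept their camera call at 94% to 103%, and with the brain score 7 of the 7 at 77.2% to 107%. As far as the marrow and brain scores track these tissues, this argues against either as the whole cause. At 20 months only replicate 3 lay within the 3-month mucosal range, so mucosa stays open. Age, as the design names it, stays open as the biological explanation, as do tissues with no list here, and with the muscle and bone score the interferon list kept its camera call at 64.5% of its median with 4 genes called in place of 20.

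Replicate 3 of 20 months lay near the 11-month libraries, with a correlation of 0.993 to them and 0.983 to the other 20-month libraries. A mislabelled sample is argued against by 47 of 52 immune genes (90.4%) lying nearer the mean of the other 20-month libraries, where those libraries themselves reached 51.9% to 94.2%. A different share of carried-over tissue is a candidate, since 2 of 2 scores, of lists added later, lay outside the other 20-month libraries and nearer the 11-month mean. The mucosal score was 1.68 against 2.46 to 2.88 in the others, and the central neuron and oligodendrocyte score 4.54 against 3.07 to 4.1. In this library Calb1 stood at 209 CPM against 42.9 to 52.6 in the others, and the airway secretory gene Bpifa1 at 3.03 against 477 to 977. Replicate 2 of 20 months had the lowest central neuron and oligodendrocyte score, 3.07 against 3.97 to 4.54 in the others of its age. Its Gfap level was 67.5 CPM against 416 to 750.

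Interferon-stimulated genes responded more to TNF with the RBM25 knockdown, with a median interaction of 2.81 on the log2 scale. A response to the vector alone is argued against by their median log2 fold change of -0.55 for the knockdown without TNF, and a vector that acts only together with TNF stays open. A generally stronger response to TNF is argued against by the NF-kB target list, whose median interaction was 5.3% of that of the interferon list. Whether more interferon was transcribed cannot be told apart at this depth, since Ifnb1 and the Ifna and Ifnl genes had 4 counts over the 3 libraries with both treatments, all in 1 library. A biological effect of RBM25 on the response to TNF may also underlie the difference and stays open.

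Several list scores had 1 library apart from the other 3 of its age. The ribosomal protein score of replicate 1 of 3 months was 7.62 against 7.84 to 7.86. That of collagen and matrix in replicate 4 of 11 months was 5.63 against 5.75 to 5.77, and that of B and plasma cells in replicate 2 of 11 months was 1.16 against 0.576 to 0.639. At 20 months, the Schwann cell score of replicate 2 was 7.41 against 8.01 to 8.04, its complement score 4.74 against 5.45 to 5.53, and the endothelial score of replicate 1 was 6.16 against 5.3 to 5.44. Among named genes, Tnf stood at 0.403 CPM in replicate 2 of 3 months against 0.0287 to 0.0907, Rem2 at 3.39 in replicate 3 of 3 months against 1.12 to 1.37, and Bglap at 29.9 in replicate 4 of 3 months against 7.53 to 10.6. Acta1 stood at 0.393 CPM in replicate 2 of 11 months against 0.132 to 0.167, and Prl at 0.0264 CPM (1 count) in replicate 3 of 11 months against 0. In all, 11 of 184 groups of 4 values had such a library, and chance gives about 1 in 20. The 3-month libraries also varied in muscle score, from 1.268 to 3.364, and tissue left in at dissection may account for the muscle and bone falls at 11 months, which stays open. The brain glia and cerebellum score was 2.877 to 3.973 at 3 months and 4.469 to 4.692 at 11 months. Central nervous tissue carried over in dissection may account for rises such as that of Calb1 at 11 months, which also stays open.

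The interaction test called 8 named genes. Log2 differences were 8.75 (Cyp1a1), 7.95 (Oas1g), 6.34 (Usp18), 6.14 (Gpnmb), -4.06 (Cilp), -3.59 (Camkv), -3.4 (Car10) and -3.24 (Lcp1). List medians were 2.81 for interferon-stimulated and 0.74 for immediate early and heat shock genes. The other lists lost their camera call with an estimated correlation. Their medians were 0.65 (MHC class I), 0.23 (senescence), -0.14 (cholesterol synthesis), -0.3 (hair cells), -0.4 (hypoxia) and -0.42 (cell cycle).

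Other splits of the same samples were counted for each comparison. For each pair of ages 1 of 35 splits, the real one, gave as many calls, the lowest share that 35 splits allow. For 20 against 3 months the real calls were 3525 against 2 at most in the other splits. They were 242 against 18 for 11 against 3 months and 2448 against 2 for 20 against 11 months. The other splits mix the ages, which puts any difference of age into the spread, so their low counts do not exclude chance. The organoid comparisons allow 10 splits each, of which 1, the real one, gave as many calls. These splits are too few for a share under 0.05, with real counts of 7546 for TNF, 8358 for the knockdown, 8314 for both against TNF and 7123 for both against the knockdown, and 0 calls at most in other splits. For the interaction, 4 of 100 splits drawn from 200 gave as many calls, the real one included. The splits shuffled the TNF label within each knockdown state, so none stands for a TNF effect equal in both states. They therefore cannot tell whether chance gave the interaction calls. The real count of the interaction was 1962 and the highest of the other splits 8937. That split kept the real labels of the control and TNF libraries and mixed those of the knockdown libraries, so that it measured the TNF effect itself, a structure of the samples, and splits mixed in both states gave 0 at most.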

How the results depend on the processing

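The covariates for mucosa, brain, and muscle and bone were chosen after the data were seen, and all other alternatives before. DESeq2's size factors and the absence of a count filter moved no count of genes by over 1.5 times. Of the named gene results, the DESeq2 test left 146 of 146 of the inner ear and 324 of 326 of the organoids unchanged. The muscle and bone score left 65 of 146 unchanged. This count takes as unchanged a called gene to which DESeq2 gave no adjusted p, and Rbm25 where it passed in neither fit. All 58 calls of inner ear lists were lost with an estimated correlation and 34 held by fry, and in the organoids 10 and 47 of 50 held. Depth limits the genes with few counts, whose fitted folds depend on the prior count.

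Against a minimum fold of 1.5, glmTreat called fewer genes by construction. The counts higher and lower were 158 and 26 for 20 against 3 months, 6 and 3 for 11 against 3 months, 3 and 0 for 20 against 11 months, 713 and 646 for TNF, 1460 and 890 for the knockdown, 1298 and 611 for both against TNF, 795 and 535 for both against the knockdown, and 79 and 33 for the interaction. Without this minimum, 5109 genes had an unadjusted p under 0.05 for 20 against 11 months.

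For 11 against 3 months, the counts higher and lower were 543 and 254 with only the libraries compared, 579 and 440 with DESeq2 and 72 and 40 with limma-trend on FPKM. The brain and the muscle and bone scores gave 12 and 7, and 0 and 1. For 20 against 11 months the brain, mucosal, and muscle and bone scores gave 741 and 733, 3 and 1, and 5 and 4. For 20 against 3 months the mucosal, and muscle and bone scores gave 866 and 401, and 832 and 988. The osteoblast list of 20 against 11 months reversed to -0.46 with the mucosal score, and the ribosomal list of 11 against 3 months to 0.1 with the muscle and bone score. The cause was not tested.

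The correlation of the effect of 11 months against effect of 20 months was 0.844 with the muscle and bone score, and 0.419, 0.372, 0.351, 0.19 and 0.309 in 5 of the 6 splits of the 3-month libraries, where fewer libraries stand in each comparison. With only the libraries compared and with limma-trend on FPKM, the effect of RBM25 knockdown without against with TNF had a correlation of 0.833 and 0.82, and the effect of TNF without against with RBM25 knockdown 0.844 and 0.829. The cause was not tested.

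With each library left out in turn, the lowest and highest counts higher were 1221 and 2010 for 20 against 3 months, 29 and 88 for 11 against 3 months, 334 and 1818 for 20 against 11 months, 3233 and 3745 for TNF, 3445 and 4068 for the knockdown, 3552 and 3814 for both against TNF, 3079 and 3495 for both against the knockdown, and 637 and 1179 for the interaction. The counts lower were 990 and 1941, 9 and 49, 453 and 1814, 3294 and 3414, 3921 and 4065, 3887 and 4121, 3027 and 3425, and 432 and 1158 in the same order. The correlations ranged from 0.456 to 0.655 for the ages, 0.734 to 0.756 for the knockdown effects, 0.753 to 0.785 for the TNF effects and -0.147 to -0.0615 for TNF genes under the knockdown.

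With a replicate block, 84 genes were higher and 46 lower at 11 than at 3 months. The numbers gave no sign of a pairing in the inner ear, where correlations of libraries with the same number ran from -0.444 to 0.438 and with different numbers from -0.392 to 0.357. In the organoids these ran from -0.163 to 0.372 and from -0.295 to 0.184. In neither experiment did every library correlate best with its own number.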

Other observations

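Other gene groups of the inner ear moved between ages. At 11 months 2 of 16 unfolded protein response genes were higher than at 3 months (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000343, and adjusted p = 0.252 with an estimated correlation), including the chaperone gene Hspa5 (log2 fold change 0.49; adjusted p by edgeR, DESeq2 or limma up to 0.308 over its alternatives), but 1 gene without any library other than replicate 2 of 3 months. Of 20 Schwann cell genes 2 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.00798, and adjusted p = 0.62 with an estimated correlation), and 0 or 1 were lower without any library other than replicate 1 of 3 months. From 11 to 20 months 8 of 17 immediate early and heat shock genes rose (10 adjusted over the list alone; camera adjusted p = 1.13e-10, and adjusted p = 0.243 with an estimated correlation), and 9 of 47 ribosomal protein genes rose (15 adjusted over the list alone; camera adjusted p = 3.43e-07, and adjusted p = 0.554 with an estimated correlation). The former were 5 without replicates 1 or 4 of 11 or of 20 months. The latter were 20 without replicate 3 of 20 months and 0 without any other library of 20 months or replicates 2, 3 or 4 of 11 months.

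In the organoids the knockdown raised Sod3, an extracellular superoxide dismutase, from 43.3 ± 1.59 to 344 ± 36.9 CPM (SD, n = 3; log2 fold change 2.99) and lowered Cd44, a hyaluronan receptor, from 65.9 ± 1.23 to 11.9 ± 3.52 CPM (log2 fold change -2.46). Hspb1, a small heat shock protein gene, fell from 32 ± 2.44 to 4.01 ± 0.202 CPM (log2 fold change -2.99). Of 16 unfolded protein response genes 5 rose and 9 fell with the knockdown (5 and 9 adjusted over the list alone; camera adjusted p = 0.184), with Herpud1 at a log2 fold change of -1.16. With both treatments against TNF, 10 of 16 mesenchymal genes rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0311, adjusted p = 0.0528 without replicate 2 of the group with both, and adjusted p = 0.58 with an estimated correlation).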
